A study of Mus musculus with 28 samples.

How the data were processed

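The 28 libraries came from mouse hair follicle stem cells, released from skin by trypsin and sorted by flow cytometry as CD34-positive, α6-integrin-positive cells, per the labels' protocols. Young mice were 6 months old and old mice 24 months. RNA-seq was done on 3 young and 3 old samples, ATAC-seq on 4 and 4, ChIP-seq for H3K27me3 on 3 and 3, and ChIP-seq for H3K4me3 and for RNA polymerase II (Pol2) on 2 and 2 each. Groups and replicate numbers were taken from the sample labels, and the series design calls the samples biological replicates.

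RNA reads were aligned with STAR 2.5.2b to GRCm38.p5, counted with featureCounts and compared with DESeq2 1.22.2, per the submitters' processing notes. The deposited RNA table holds 1 comparison of old with young and no values per sample. Its columns give the mean normalized signal over all libraries, the log2 fold change with its standard error, a test score (the Wald statistic), the p-value and the adjusted p-value, per the file headers. Its header names the fold change as old against young. Whether the log2 fold change was shrunken is not given in the sources used here. The authors' table lists only genes with an adjusted p-value up to 0.1, and p-values carry 8 decimals, so the smallest read 0.

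ATAC-seq reads were aligned with BWA 0.7.12 to GRCm38, per the submitters' processing notes. The peak caller and the test are not given in the sources used here. The deposited ATAC-seq table holds a whole-number count per peak and library, the log2 ratio of the young to the old mean count, and a −log10 p-value, per the file headers. The authors' log2 ratio equals the ratio of the unscaled group means, so that positive means higher in young. Every listed peak has a deposited −log10 p-value of at least 2.00 and an absolute log2 ratio of at least 0.50. The table is therefore a selection of peaks made on the same libraries and grouping that were tested here. Whether the counts were thinned or scaled by the authors before they were deposited is not given in the sources used here.

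ChIP-seq reads were aligned with BWA 0.7.15 to GRCm38, peaks were called with MACS2 2.2.7.1 and groups were compared with DiffBind 2.14.0, per the submitters' processing notes. The deposited tables hold, for each merged peak, the log2 of the mean normalized read count in young and in old samples, their log2 difference, a p-value and a false discovery rate (FDR), per the file headers. The normalization setting is not given in the sources used here. The authors' log2 difference is young minus old and was turned to old over young here. Each table has a lowest level, which is no measured count, and a fold change against it is no measured bound. Positions and gene annotations of peaks are those of the deposited tables, on GRCm38.

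Only the ATAC-seq table has values per sample, so it was the only one tested anew. Old and young libraries were compared with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr, two-sided, Benjamini-Hochberg adjustment) in R 4.3.3. The filter removed no peak. Because TMM scaling on a selected list recentres any change that most listed peaks share, the same test was also run without scaling, with equal library sizes. That setting was chosen after seeing the data. In a test on simulated data with the 7849 peaks and the real library sizes, 7.94% of peaks changed by 0.5 on the log2 scale were recovered, 51.5% of those changed by 1 and 97.2% of those changed by 2. There were 4 false calls, 3.57% of all calls. The simulated peaks were not selected on the grouping, and their changes went in both directions. These rates therefore do not carry over to calls on the listed peaks. For RNA and ChIP-seq the authors' adjusted p-values were used at the same threshold of 0.05, and peaks or genes past it are said to be called.

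No pair of ATAC-seq libraries agreed within sampling noise, since the lowest chi-square per degree of freedom between any pair was 10.8. Totals of the ATAC-seq counts are sums over listed peaks and not library depths. The depth of the RNA and ChIP-seq libraries is unknown.

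A promoter peak is one annotated within 1 kb of a transcription start site. A bivalent promoter is an H3K4me3 promoter peak that overlaps an H3K27me3 peak by at least 1 bp (bedtools 2.31.1). Classes of promoters were compared by the difference of median log2 fold changes with a permutation test (100000 permutations, so that the smallest possible p is 1e-05) and by Fisher's exact test, all two-sided unless said otherwise. Fold changes of different assays were joined by gene, as the mean over a gene's promoter peaks, and correlated across genes with permutation p-values. P-values were adjusted by the Benjamini-Hochberg method within each family. These were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Gene lengths came from a RefSeq gene table of assembly GRCm38.p6, used for lengths only.

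The tests, the gene lists and the rule for named genes were fixed before the data were examined. The 21 gene lists cover hair follicle stem cell (HFSC) identity, interfollicular epidermis and terminal differentiation, hair shaft and inner root sheath, sebaceous gland and lipid, basement membrane, integrins with focal adhesion and mechanosensing, immediate early and heat shock genes that tissue dissociation can induce, the Wnt pathway, the BMP and TGF-β pathway, the Notch, Hedgehog and FGF pathways, Polycomb and Trithorax, cell cycle and senescence, fibroblasts, immune cells, melanocytes, endothelium with muscle and glia, inflammation and stress signalling, and 4 families defined by symbol: developmental regulators, cytosolic ribosomal proteins, mitochondrially encoded genes and keratins. Members with a called peak anywhere at the gene were counted in each direction and compared with all other genes that have a peak by Fisher's exact test. The same counts at promoter peaks alone, the direction of listed ATAC-seq peaks at bivalent promoters, the share of H3K4me3 promoters with a listed ATAC-seq peak, and the draws of promoters matched on level were added after seeing the data. Fisher's exact test of direction for the ribosomal protein genes in RNA was not fixed in advance either. The RNA table lists selected genes only, so its lists were counted and not tested with camera or fry. Per assay, the rule named the 8 genes with the largest fold change in each direction among called features, with every old library on the same side of every young one where libraries were given. It added up to 3 called members per list with the smallest adjusted p, and Cd34, Itga6, Col4a1, Col4a2, Lama5, Lamb3, Sox9, Lhx2 and Ezh2 whatever their values. Predicted gene models were left out.

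Alternatives tried were DESeq2 1.42.0, limma 3.58.1 with voom, other scalings, other thresholds, a minimum mean of 50, leaving out each ATAC-seq library, the replicate number as a block, a larger promoter distance of 3 kb, an overlap of 50%, the stronger 50% of peaks, and classes matched on mean level in 20 bins.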

Results

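Hair follicle stem cells sit in the bulge of the hair follicle, where they carry CD34 and α6-integrin on their surface and renew the follicle at each hair cycle. Cells from young (6 months) and old (24 months) mice were profiled for RNA with 3 samples per age and for open chromatin by ATAC-seq with 4 per age. ChIP-seq covered H3K27me3, the histone mark left by Polycomb, with 3 samples per age. It also covered H3K4me3, a mark of active and poised promoters, and Pol2, the enzyme that transcribes genes, with 2 samples per age each. The series title poses the question whether bivalent promoters, which carry H3K4me3 and H3K27me3 together, become less accessible with age. Total ATAC-seq counts over the listed peaks ran from 2456110 to 2773284 in the young libraries and from 1572998 to 1946804 in the old ones.

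The RNA comparison asks which transcripts differ between old and young stem cells. With the sign as the header of the authors' deposited table gives it, the largest increases in old cells were of Peg3, an imprinted gene for a zinc finger protein, with a log2 fold change of 1.38 (deposited SE 0.13), and of Sox21, a transcription factor gene of the hair lineage, both with adjusted p listed as 0. The authors' deposited table also lists higher RNA for Cpa4, a carboxypeptidase (1.21, adjusted p 2.36e-06), Slitrk6, a membrane protein of neuronal growth (1.16, 5.6e-07), Galnt14, an enzyme of protein glycosylation (1.11) and Nptx1, a secreted pentraxin (1.07). The largest decreases in the authors' deposited table were of Mef2c, a MADS-box transcription factor (−1.82, SE 0.22), Tcf24, a basic helix-loop-helix factor (−1.55, SE 0.20), Cd74, the invariant chain of major histocompatibility class II (−1.36, adjusted p 2.36e-06), and Rorb, a nuclear receptor (−1.14, 0.000178). It lists as lower, too, the guidance cue Sema3d (−1.04), the B-lineage factor Ebf1 (−1.02) and Timp3, an inhibitor of matrix metalloproteinases (−1.01), all from the authors' deposited table.

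Genes for cytosolic ribosomal proteins made up the largest group. All 43 that are listed were higher in old cells and 38 were called, with log2 fold changes from 0.35 to 0.71 in the authors' deposited table, among them Rps25 (0.67), Rps7 (0.60) and Rps3 (0.60). Of the other listed genes 318 were higher and 236 lower, and the difference in direction had a Fisher's exact p of 2.32e-10. This test was not fixed in advance, and genes are not independent replicates. All 4 listed members of the Notch, Hedgehog and FGF list were called higher. The authors' deposited table gives 0.99 for Hhip and 0.56 for Ptch1, both Hedgehog targets, and 0.74 for Tgfa, a ligand of the EGF receptor. The basement membrane list had 1 called member in each direction, Tnc (0.65), which encodes tenascin C, and Smoc2 (−0.52), as the authors' deposited table has them. Of 4 listed developmental regulators, Sox21 was called higher and Gata6 lower, at −0.78 in the authors' deposited table. Of 4 immediate early and heat shock genes, Hspa8 alone was called (0.52 in the authors' deposited table), and of 2 Polycomb and Trithorax genes Phf1 alone (−0.63 in the same authors' deposited table). Single called genes came from the keratin and inflammation lists, which share Krt16 (0.75 in the authors' deposited table), from the BMP and TGF-β list with Skil (0.38 in the authors' deposited table), from the hair shaft list with Ptch1, and from the immune list with Cd74, 1 of its 2 listed members. No member was called among the 1 listed gene of HFSC identity, 1 of the Wnt pathway, 2 of integrins and adhesion, 2 of fibroblasts and 1 of endothelium, muscle and glia. The interfollicular, sebaceous, cell cycle, melanocyte and mitochondrially encoded lists had no listed gene, and neither did the sort markers Cd34 and Itga6.

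Of the 597 genes in the authors' deposited table, 339 had an adjusted p under 0.05, 227 higher and 112 lower in old cells. These directions rest on the header's sign. Were it reversed, the 43 ribosomal protein genes and all others named as higher would be lower in old cells, and the reverse. If the chromatin tables were the reversed ones instead, the ATAC-seq, H3K27me3, H3K4me3 and Pol2 directions given below would turn. Because only selected genes are listed, no list could be set against all expressed genes or be adjusted over the list alone.

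**Figure D1:**
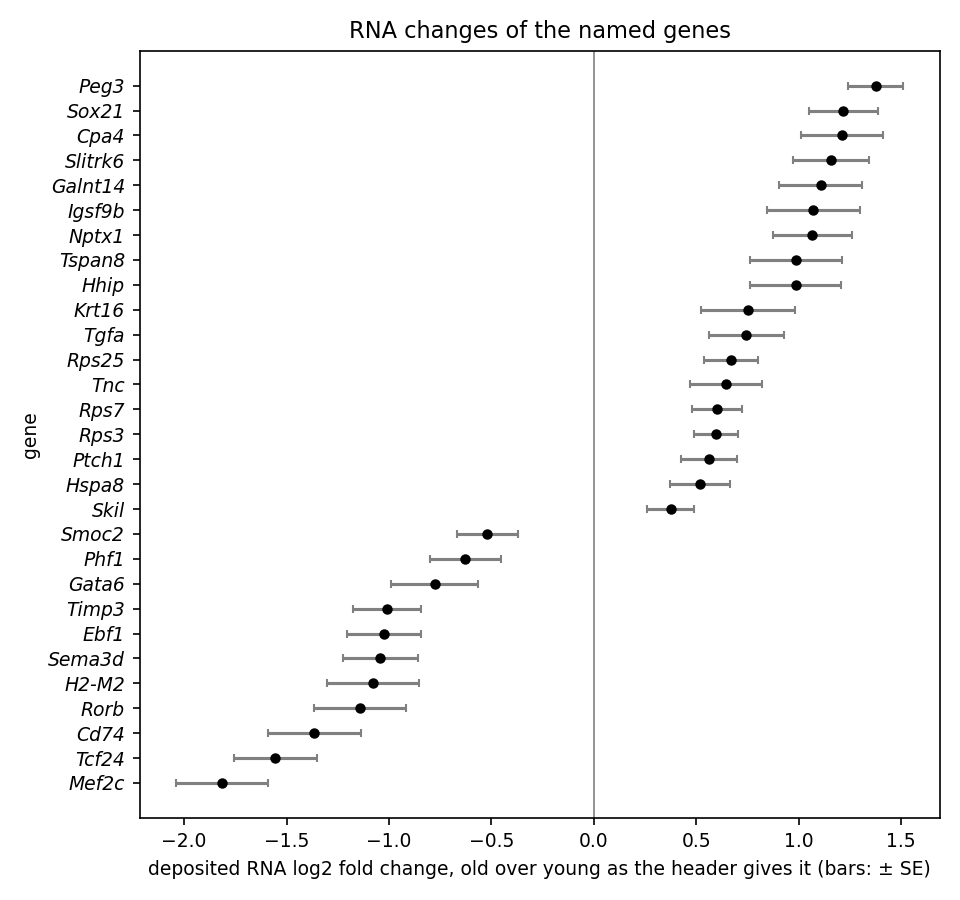
Log2 fold changes of RNA in old over young cells (horizontal axis) for each named gene (vertical axis), from the authors' deposited table, with bars of 1 deposited standard error. Values run from −1.82 for Mef2c to 1.38 for Peg3.

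ATAC-seq asks where chromatin is more or less open in old cells. Of 7849 listed peaks, 6745 (85.9%) had a lower mean count in old cells and 1104 a higher one. A peak in an intron of Usp29, a gene of the imprinted Peg3 region (chromosome 7, 6749151 to 6749600), fell from 281 ± 70 counts in young to 42.8 ± 17.0 in old libraries (SD, n = 4 each). A distal peak annotated to Dio3, an imprinted gene for a thyroid hormone deiodinase (chromosome 12, 110346901 to 110347200), fell from 119 ± 36.6 to 19.0 ± 18.1 (SD, n = 4 each). A distal peak at Edn1, which encodes endothelin (chromosome 13, 42478001 to 42478150), fell from 54.5 ± 23.7 to 7.75 ± 5.19, and a distal peak at Lhx2, a transcription factor gene of follicle stem cells (chromosome 2, 38382751 to 38383150), from 201 ± 35 to 66.5 ± 22.2 (SD, n = 4 each).

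The largest rise was in an intron of Sult2a3, a sulfotransferase gene (chromosome 7, 14114351 to 14115200), from 78.8 ± 41.1 to 658 ± 146 counts, and the nearby gene Sult2a6 had a distal peak that rose from 61.0 ± 35.7 to 288 ± 30.3 (SD, n = 4 each). Peaks also rose in an intron of Csmd1 (chromosome 8, 15947601 to 15948100), from 68.5 ± 14.9 to 374 ± 98.7, in an intron of Itpr1, a calcium channel gene (chromosome 6, 108337151 to 108337800), from 173 ± 42.5 to 606 ± 83.0, and in an exon of Rorb (chromosome 19, 18959901 to 18960450), from 106 ± 55.7 to 301 ± 113 (SD, n = 4 each). These 9 peaks were called with either scaling in edgeR, with FDRs from 1.56e-07 to 0.0460 with TMM and from 8.09e-05 to 0.0133 without scaling. These FDRs, like all edgeR FDRs given here, were adjusted over peaks already selected on the same grouping. They rank the listed peaks and do not bound the share of false calls.

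Members of most lists had more lower than higher listed peaks, while the genes called with TMM were nearly all higher. The selection largely fixed those higher calls. Listed log2 ratios are at least 0.50 in size, TMM raises them by a median of 0.59, and 1088 of the 1104 higher peaks were called. Lists were counted with TMM only. HFSC identity genes had 41 lower and 5 higher peaks. With TMM 1 gene was called lower and 5 higher, and adjusted over the list alone 0 lower and 5 higher, including Foxc1 (log2 fold change 1.42 with TMM, 0.86 without scaling) and Nfib (1.11 and 0.50, unscaled FDR 0.0744). Basement membrane genes had 41 lower and 11 higher peaks, with 8 genes called higher, among them Smoc2 (1.45 and 0.86), Crim1 (2.04 and 1.46) and Hspg2 (1.26 and 0.68). Wnt pathway genes had 48 lower and 11 higher peaks and 8 genes called higher, with Lgr6, a stem cell receptor, at 1.56 and 0.96. The integrin and adhesion list had 44 lower and 5 higher peaks and 5 genes called higher (Itgb1 1.75 and 1.14), the Notch, Hedgehog and FGF list 43 and 7 with 6 called higher (Notch1 1.39 and 0.83), and the BMP and TGF-β list 65 and 5 with 3 called higher (Acvr2a 1.92 and 1.34). Developmental regulators had 88 lower and 5 higher peaks. Among them 1 gene was called lower and 4 higher, or 0 and 4 adjusted over the list alone. The immediate early and heat shock list had 35 lower and 5 higher peaks with 3 genes called higher, the inflammation list 30 and 2 with 2 called higher (0 adjusted over the list alone), the cell cycle list 10 and 3 with 3, the Polycomb and Trithorax list 7 and 3 with 3, and the hair shaft list 16 and 2 with 2. Among other cell types, fibroblast genes had 4 lower and 4 higher peaks with 4 genes called higher (Crabp1 1.15 and 0.56), endothelium, muscle and glia 11 and 2 with 2, melanocytes 5 and 2 with 1, and immune genes 0 and 1 with 1 (H2-Eb1 1.45 and 0.87). The interfollicular (22 lower), sebaceous (10), keratin (10) and ribosomal (9) lists had lower peaks only and no call, and mitochondrially encoded genes had no listed peak. Where no other number is given, the counts adjusted over the list alone were the same. None of the 20 lists with a peak differed from other genes in its share of called genes (lowest adjusted p 0.273).

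The deposited −log10 p-values of the ATAC-seq peaks followed those without scaling (rho 0.846) more closely than those with TMM (0.17), which does not tell which scaling is right. With TMM scaling 55 peaks were called lower and 1088 higher (4.81% lower), and without scaling 3643 lower and 426 higher (89.5% lower). The scalings differ by a median shift of 0.59 on the log2 scale, so the TMM values are changes relative to the median listed peak. The sort marker Cd34 shows the effect: a distal peak with 171 ± 76.6 counts in young and 75.8 ± 18.1 in old libraries (SD, n = 4 each) had an edgeR FDR of 0.503 with TMM and 0.0228 without scaling. A Col4a2 intron peak, at 207 ± 26.1 and 121 ± 35.6 (SD, n = 4 each), had FDRs of 1.00 and 0.0392. Another Col4a2 intron peak, at 331.5 ± 134 and 213 ± 42.5 (SD, n = 4 each), was called with neither scaling (FDR 0.0630 without scaling). Calls without scaling dropped to 1409 lower and 141 higher without old replicate 3. They were 1846 and 181 without young replicate 3, 2099 lower without young replicate 4, 1867 lower without old replicate 4, and 265, 254 and 246 higher without young replicate 2, old replicate 1 and old replicate 2. With TMM, 34 peaks were lower without young replicate 3.

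**Figure D2:**
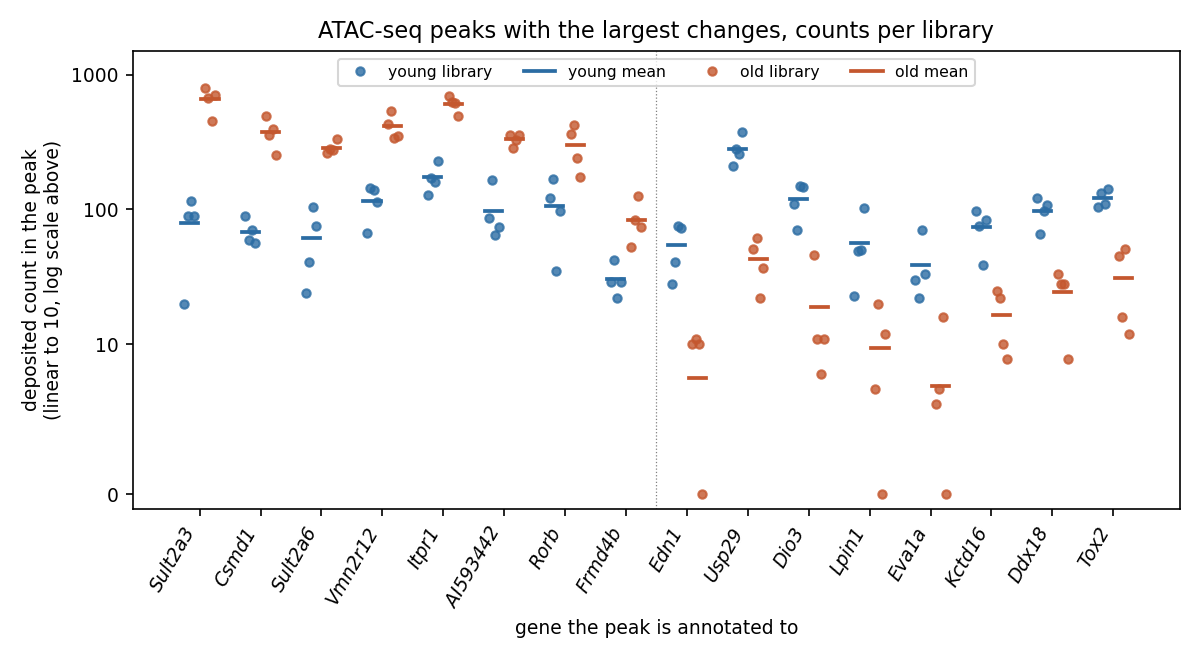
Deposited ATAC-seq counts (vertical axis, linear to 10 and logarithmic above) in each young and old library for the peaks with the largest changes (horizontal axis, by annotated gene), with bars at the group means. The Sult2a3 peak has a mean of 78.8 counts in young and 658 in old libraries, and the Usp29 peak 281 and 42.8.

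H3K27me3 asks where Polycomb repression differs. In old cells the mark fell at promoters of developmental regulators and Wnt genes. The authors' deposited table gives log2 fold changes of −1.03 for Sox17, a factor of endoderm and vessels (chromosome 1, 4486654 to 4503214, FDR 1.29e-11), −1.01 for Dlx1 (2.03e-08) and −0.72 for Dlx6 (3.27e-09), both homeobox genes. At Wnt genes the authors' deposited table gives −5.76 for a promoter peak of Wnt6 (FDR 2.03e-08), −1.62 for Wnt7b (1.18e-06) and −0.68 for Sfrp2 (0.000158). The promoter of Nr4a2, an immediate early nuclear receptor gene, had −1.32 (FDR 2.2e-20) and that of Cdkn2a, the senescence gene long known as a Polycomb target, −0.59 (2.99e-05) in the authors' deposited table.

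Counts at promoters were added after seeing the data. Of 112 developmental regulators with a promoter peak, 74 (66.1%) were called lower and none higher, against 13.1% of other genes (adjusted p for lower calls 1.38e-35). Adjusted over the list alone, 91 were lower and 0 higher. Of 22 Wnt genes 11 (50.0%) were called lower, against 14.2% of others (adjusted p for lower calls 0.000771), and 16 adjusted over the list alone. In the hair shaft list 5 of 10 genes were called lower (7 adjusted over the list alone, and 1 higher), with a list p of 0.0542 after adjustment. There the authors' deposited table gives −0.67 for Gata3, −0.86 for Cux1 and −0.53 for Msx1. The hair shaft list shares genes such as Gata3 and Msx1 with the developmental regulators, so these lists are not independent. The Notch, Hedgehog and FGF list had 7 of 19 lower (8, and 3 higher, adjusted over the list alone), with Fgf9 at −1.40 and Dll4 at −0.58 in the authors' deposited table. For BMP and TGF-β genes 4 of 9 were lower (4 adjusted over the list alone), with Bmp3 at −1.13 and Bmp4 at −0.81 in the authors' deposited table. The list p-values were 0.0641 and 0.117 after adjustment. In the test fixed in advance, of calls in either direction at peaks anywhere at a gene, 3 lists passed: developmental regulators (adjusted p 1.85e-29), Wnt (0.0105), and cell cycle and senescence (0.0105), with 4 genes called lower and 3 higher of 10. For lower calls alone hair shaft (0.0116), Notch, Hedgehog and FGF (0.0116), and BMP and TGF-β (0.0494) passed as well, but in either direction they did not (0.184, 0.514 and 0.766), and cell cycle did not for lower calls (0.0638).

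At the promoters of the remaining lists few genes were called. Lower calls were at 2 of 4 cell cycle genes (3 adjusted over the list alone), 1 of 3 HFSC identity genes (1), which was Runx1 at −0.66 in the authors' deposited table (at peaks anywhere 1 of 8 was lower and 3 were higher, such as Postn at 4.07), 1 of 3 Polycomb and Trithorax genes (2), 2 of 6 sebaceous genes (2) and 1 of 4 immediate early genes (2). They were at 1 of 9 interfollicular genes (1 adjusted over the list alone), 1 of 12 basement membrane genes (4), 1 of 6 integrin and adhesion genes (2, and 1 higher), 2 of 13 inflammation genes (3, and 1 higher), and 2 of 15 keratins (3), where Krt12 was called higher (0.80 in the authors' deposited table). Among other cell types they were at 2 of 8 fibroblast genes (5 adjusted over the list alone), 1 of 9 endothelial, muscle and glial genes (2) and 0 of 3 melanocyte genes (1). Of 11 immune genes 0 were called lower and 1 higher, Laptm5 at 0.46 in the authors' deposited table. Elsewhere than at promoters, distal peaks of the immune genes Csf1r and Tyrobp had 0.88 and 0.66 in the authors' deposited table. The 1 ribosomal gene with a promoter peak was not called, and no mitochondrially encoded gene had a peak. The largest increases in the authors' deposited table, 6.56 at Myh7b and 6.02 at Chst15, were at peaks where the young level was the table's lowest. In the same way the largest decreases in the authors' deposited table, −6.95 at Pkdcc and −6.81 at Aprt, had the old level at the table's lowest.

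Over all 67985 peaks of the authors' deposited table, 1767 were called lower and 1811 higher, with a median log2 fold change of 0.12. At promoters 773 were lower and 264 higher, and at distal peaks 493 and 757. Developmental promoters carry more of the mark than others (median level 11.9 against 7.68 for other peaks before matching). Among 10000 draws of other promoter peaks matched on level, the median number called lower was 28, against 75 of the 126 developmental peaks (one-sided p 0.0001, the smallest the draws can give). Wnt genes and the other lists were not matched on level.

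**Figure D3:**
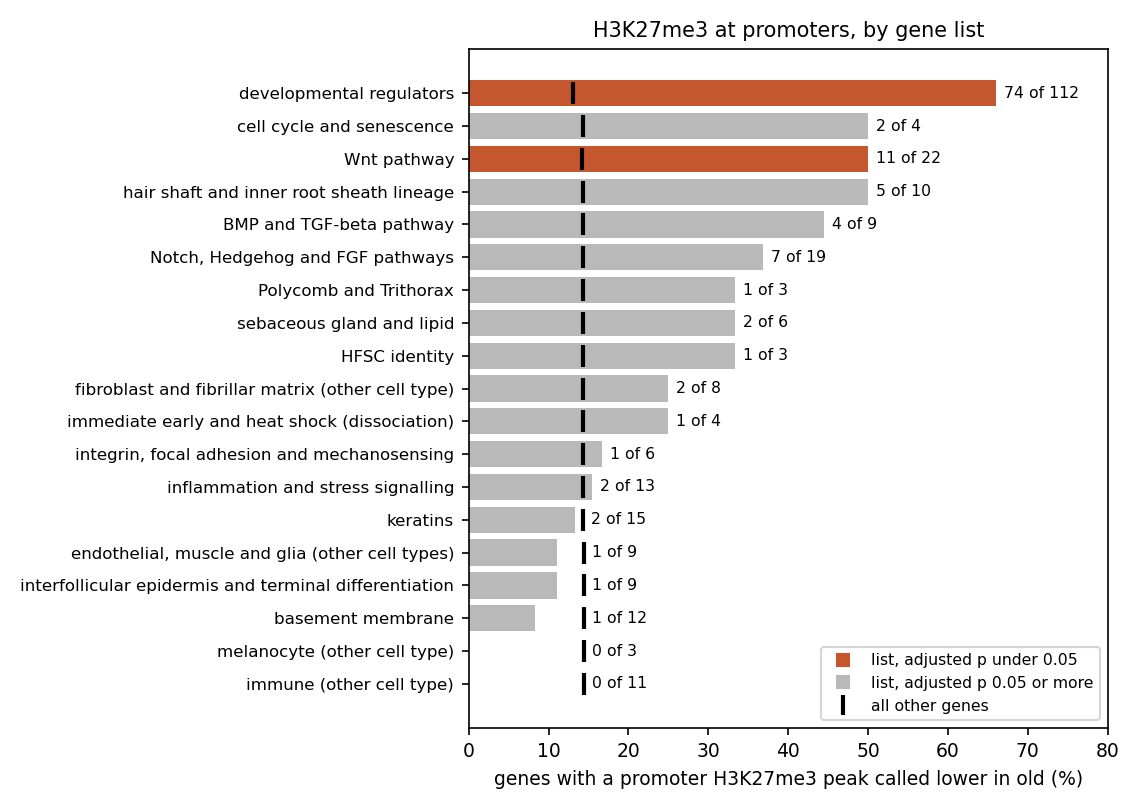
Share of genes with a promoter H3K27me3 peak called lower in old cells (horizontal axis, percent) for each gene list (vertical axis), with the share among all other genes as a black tick. Developmental regulators reach 66.1% and the Wnt pathway 50.0%.

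H3K4me3 was lower in old cells at promoters of nearly every gene group. The authors' deposited table gives −2.52 for Sox21 (chromosome 14, 118229355 to 118239642, FDR 6.83e-14), −2.56 for Lamb1, a laminin chain of basement membranes (5.12e-11), and −2.08 for Hhip, the Hedgehog inhibitor (3.93e-09). Stem cell genes were among them, with −1.95 for Gli1, −1.76 for Fgf18 and −1.59 for Bmp6 in the authors' deposited table. At promoters of the genes chosen in advance the authors' deposited table has −0.99 for Cd34 (FDR 0.00156), −1.54 for Itga6, −1.68 for Sox9, −1.56 for Lhx2, −1.48 for Ezh2, −1.53 for Lama5, −1.48 for Col4a1 and −1.16 for Lamb3. An exon peak of Cd34 (−0.07, FDR 0.92) and an intron peak of Lamb3 (−0.25, FDR 0.604) were not called in the authors' deposited table. Higher H3K4me3 in the authors' deposited table was found in introns of Mdga2 (2.27) and Cldn34d (1.77), and at a promoter peak of Sp140 (5.79), where the young level was the table's lowest.

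In every list at least 6 of 7 genes with a promoter peak were called lower: 20 of 21 for HFSC identity, 110 of 112 developmental regulators, 47 of 47 Wnt, 34 of 35 basement membrane, 50 of 50 integrin and adhesion, 44 of 44 Polycomb and Trithorax, 52 of 52 ribosomal and 38 of 38 cell cycle genes. Likewise it was 41 of 41 for BMP and TGF-β, 35 of 35 for Notch, Hedgehog and FGF, 26 of 26 for immediate early genes, 26 of 27 for inflammation, 16 of 16 sebaceous, 13 of 13 interfollicular, 11 of 11 hair shaft genes and 11 of 11 keratins. Other cell types had 10 of 10 fibroblast, 3 of 3 immune, 3 of 3 melanocyte and 6 of 7 endothelial, muscle and glial genes, the last being 7 adjusted over the list alone, while every other count stayed the same adjusted over the list alone. Among other genes the share was about 97.9%, and no list of 20 differed from it (each adjusted p 1). Over all 21390 peaks of the authors' deposited table, 16921 were called lower and 60 higher, with a median log2 fold change of −1.37. With 2 samples per age and no values per sample, these counts rest on the authors' normalization.

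Pol2 was lower in old cells as well, at promoters of adhesion, signalling and stem cell genes as at those of most other genes. In the authors' deposited table the promoter of Itga6, which encodes the α6-integrin used for sorting, had −4.27 (FDR 2.37e-06), Lamb3, a chain of laminin-332, −2.69 (0.00229) and Actn1, an actin crosslinker, −3.07 (0.000353). The Wnt receptor gene Fzd5 had −7.05 (7.38e-09) and Fzd8 −2.84, and Egfr had −3.67, in the authors' deposited table. For Ptk2, the focal adhesion kinase gene (−7.40), and Arid1a, a chromatin remodeller (−7.95), the old level in the authors' deposited table was its lowest. Stem cell genes had −2.51 for Tcf7l2, −2.09 for Sox9, −1.68 for Krt15 and −1.60 for Cd34 (FDR 0.0344), while Lhx2 had −1.36 (0.089) and was not called in the authors' deposited table. Ezh2, the Polycomb methyltransferase that deposits H3K27me3, had −4.86 (0.0152 in the authors' deposited table).

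Immediate early genes and ribosomal protein genes were called lower less often than other genes. Mean level was not matched here. Across Pol2 promoter peaks, change and level had a Spearman's rho of 0.261, with smaller decreases at higher levels. In the test fixed in advance, at peaks anywhere at a gene, 16 of 27 immediate early and heat shock genes (59.3%) were called lower against 84.7% of other genes (Fisher's exact test, adjusted p 0.0132), and 11 adjusted over the list alone. Ribosomal protein genes had 33 of 54 (61.1%) against 84.9% (adjusted p 0.000433), and 36 adjusted over the list alone. At promoters, a count added after seeing the data, 11 of 26 immediate early and heat shock genes (42.3%) were called lower, against 88.9% of other genes (Fisher's exact test, adjusted p 2.73e-07), and 7 adjusted over the list alone. Ribosomal protein genes had 33 of 53 (62.3%) against 89.0% (adjusted p 5.13e-06), and 39 adjusted over the list alone. Rps19 at −3.40 and Egr2 at −2.67 in the authors' deposited table were among those called. The other lists did not differ from the rest by this test: 12 of 17 HFSC identity genes were lower (adjusted p 0.178), 10 of 15 inflammation genes (0.139), 23 of 26 integrin and adhesion genes (24 adjusted over the list alone), 21 of 25 developmental regulators (22) and 14 of 16 Polycomb and Trithorax genes (15). It was 12 of 13 for Notch, Hedgehog and FGF, 11 of 13 for BMP and TGF-β, 10 of 12 for Wnt, 10 of 10 for cell cycle, 8 of 9 for basement membrane, 5 of 6 keratins, 5 of 5 sebaceous, 3 of 3 interfollicular and 2 of 2 hair shaft genes. Fibroblast genes had 1 of 1, endothelium, muscle and glia 1 of 1, immune genes 0 of 1 and melanocytes no promoter peak, and these counts did not move adjusted over the list alone. Of 6789 peaks in the authors' deposited table, 3589 were called lower and 3 higher, with a median of −1.72. The named higher ones were Gpm6a (2.91) and Itih5 (4.09, young level at the lowest) in the authors' deposited table.

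Bivalent promoters are the subject of the series title. Of 13505 H3K4me3 promoter peaks, 2046 (15.1%) overlapped an H3K27me3 peak. Developmental regulators were often among them, with 79 of 112 genes (70.5%) against 14.8% of other genes (Fisher's exact p 1.63e-39). Bivalent promoters more often held a listed ATAC-seq peak that was lower in old cells, 267 of 2046 (13.0%) against 551 of 11459 (4.81%), with an odds ratio of 2.97 (Fisher's exact p 1.61e-38) that held at matched peak width (4.50% of the others, p 1.11e-22). Higher ATAC-seq peaks lay at 7 (0.342%) and 31 (0.271%), with a Fisher's exact p of 0.503. Lower and higher are directions of unscaled counts here. The listed peaks are selected ones, so how many ATAC-seq peaks each class held in all is unknown. Mean H3K4me3 level, with a median of 9.14 at bivalent and 10.4 at other promoters, was not matched. H3K27me3 itself was called lower at 456 of 1829 promoter peaks that overlap H3K4me3 (24.9%) and higher at 14, against 317 of 6579 (4.82%) and 250 of the others. The medians were −0.37 and 0.05 (permutation p 1e-05, the smallest possible, adjusted 2e-05). Matched on mean level, 23.7% were called lower against 7.89%, with medians of −0.37 and −0.01 (permutation p 1e-05).

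Among listed ATAC-seq promoter peaks, the 188 with both marks had a median log2 fold change of −0.64 and the 309 with H3K4me3 alone −0.59, a difference of −0.05 (permutation p 0.00753, adjusted 0.00753 over 4 class comparisons) that was −0.024 (p 0.242) when matched on level. Lower in old were 186 of the 188 (98.9%) and 295 of the 309 (95.5%), with a Fisher's exact p of 0.0366. That p was 0.168 with an overlap of 50%, 0.119 in the stronger 50% of peaks and 0.0614 matched on level. Calls with TMM were 1 lower and 2 higher against 0 and 14 (Fisher's exact p 0.176, edgeR). H3K4me3 had a median of −1.50 at bivalent and −1.41 at other promoters (permutation p 1e-05, adjusted 2e-05). The difference was −0.02 (permutation p 0.0309) in the stronger 50% of peaks. It was −0.07 matched on level and −0.16 with an overlap of 50% (permutation p 1e-05 for both). Shares of H3K4me3 peaks called lower went either way, with 93.7% at bivalent and 94.4% at other promoters, and 93.7% and 89.4% matched on level. Pol2 had −1.51 at 30 bivalent and −2.36 at 3418 other promoters (permutation p 3e-05, adjusted 4e-05), and matched on level the difference fell from 0.85 to 0.50 (p 0.198). Peaks are not independent replicates, so these p-values describe the peaks of these libraries.

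**Figure D4:**
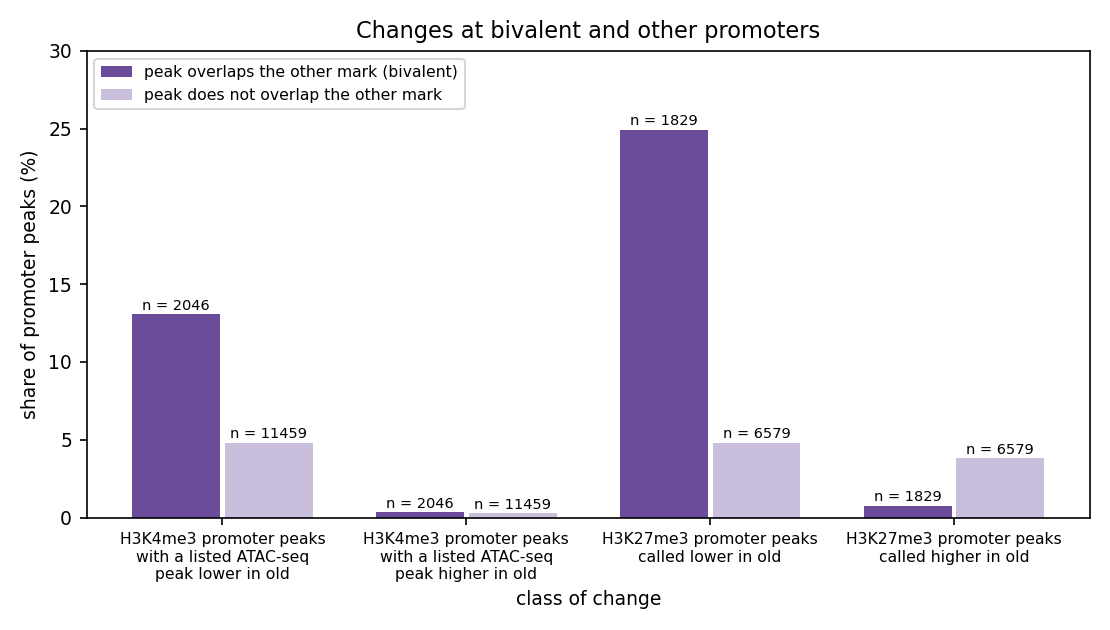
Share of promoter peaks (vertical axis, percent) with each class of change (horizontal axis) at promoters where the peak overlaps the other histone mark and at those where it does not, with the number of peaks above each bar. Listed ATAC-seq peaks with lower unscaled counts lie at 13.0% and 4.81%, and H3K27me3 was called lower at 24.9% and 4.82%.

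The layers were then joined by gene to ask whether RNA moved with chromatin. With signs as the headers give them, several genes with lower RNA in old cells held higher ATAC-seq peaks, and genes with higher RNA held lower ones. In the authors' deposited table RNA was −1.82 for Mef2c, whose 5 listed ATAC-seq peaks were all higher (mean 1.03), and −1.14 for Rorb, whose peak was also higher (1.51). By contrast RNA was 1.38 for Peg3 and 1.16 for Slitrk6 in the authors' deposited table, and it was higher for Sox21, too. Their 1, 11 and 6 listed ATAC-seq peaks were all lower (means −0.93, −0.86 and −1.11), as were 85.9% of all listed peaks. Exceptions include Tgfa, with higher RNA and a higher ATAC-seq peak (0.58), and Sema3d, with lower RNA and 2 lower ATAC-seq peaks (mean −0.61). For Tcf24 and Timp3, chosen for this after values were seen, promoter H3K27me3 was −2.26 and −2.85 in the authors' deposited table, in the same direction as RNA.

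Over 156 genes with any listed ATAC-seq peak, Spearman's rho with RNA was −0.341 (permutation p 3e-05, adjusted 0.00012) and Pearson's r −0.433 (p 1e-05, adjusted 4e-05). Of genes with lower RNA, 43 had lower and 21 higher ATAC-seq signal, and of those with higher RNA 89 and 3 (Fisher's exact p 5.12e-07). At promoters, over 28 genes, rho was −0.376 (permutation p 0.0504, adjusted 0.101) and r −0.592 (p 0.00124, adjusted 0.00496). Promoter H3K27me3 ran with RNA over 66 genes, with rho 0.489 (permutation p 1e-05, adjusted 4e-05) and r 0.308 (p 0.00365, adjusted 0.0073). Neither H3K4me3 (457 genes, rho −0.0185, permutation p 0.691, adjusted 0.691) nor Pol2 (175 genes, rho −0.0598, p 0.435, adjusted 0.58) was correlated with RNA by rank. Pearson's r was −0.0954 for H3K4me3 (permutation p 0.0417, adjusted 0.0556) and −0.0605 for Pol2 (p 0.426, adjusted 0.426). For H3K4me3 r passed with the strongest promoter peak (−0.123, adjusted p 0.0113) and for RNA genes with adjusted p under 0.05 (−0.188, adjusted p 0.00844), but not with any annotated peak (−0.0455, 0.321). These 4 relations are across genes, which are not independent replicates, and only listed RNA genes enter. Of 6 relations between chromatin layers, 3 passed: ATAC-seq with H3K4me3 (482 genes, rho 0.204), H3K4me3 with Pol2 (3078 genes, 0.184) and H3K4me3 with H3K27me3 (1647 genes, −0.135), each with permutation p 1e-05 and adjusted p 2e-05. For ATAC-seq with H3K27me3 rho was −0.0206 (304 genes, permutation p 0.718), for ATAC-seq with Pol2 −0.109 (70 genes, 0.367) and for H3K27me3 with Pol2 −0.0135 (102 genes, 0.892).

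**Figure D5:**
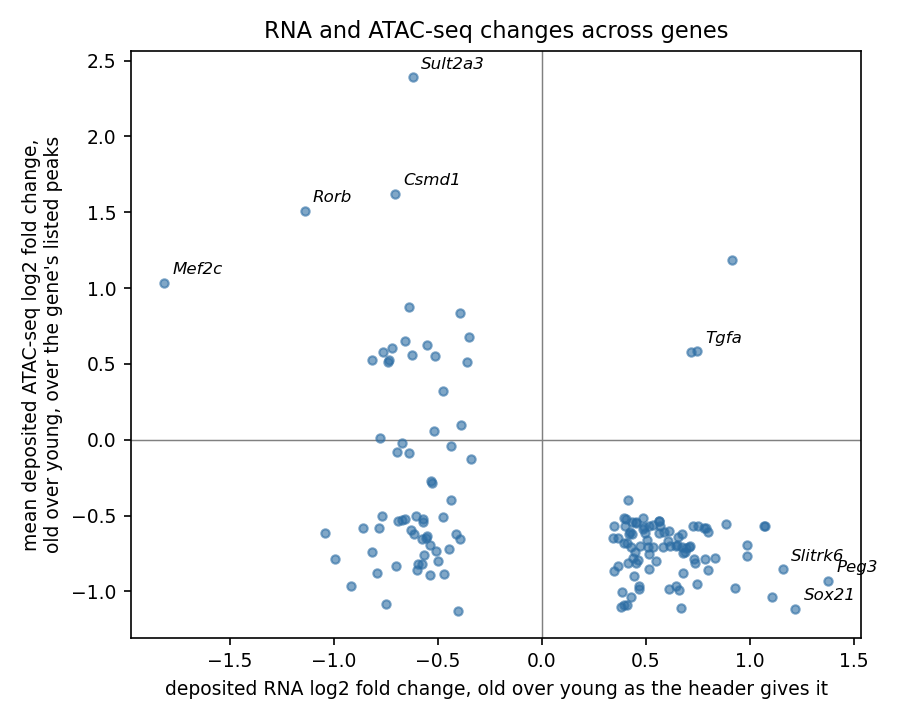
Log2 fold change of RNA (horizontal axis) against the mean log2 fold change of a gene's listed ATAC-seq peaks (vertical axis), old over young, with 1 point for each of 156 genes. Genes with higher RNA have lower ATAC-seq signal in 89 cases and higher in 3. Those with lower RNA have lower ATAC-seq signal in 43 cases and higher in 21.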

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

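The tests of a reversed RNA sign, of a shift shared by every assay and of strain segments were chosen only after the results were seen. Each of 80 groups of 4 ATAC-seq libraries at the named peaks was searched for a library far from the other 3 by Dixon's ratio, which chance gives in about 1 in 20 groups, and 6 were found. In young replicate 4 the Crim1 peak had a count of 22, against 48 to 51 in the other young libraries. Old replicate 4 had a count of 0 at the Edn1 peak, where the other old libraries had 10 to 11. Old replicate 1 accounts for 3 of the 6, with 46 at Dio3 (others 8 to 11), 214 at Foxc1 (114 to 127) and 829 at Wnt5b (539 to 562). Inhbb had 144 in old replicate 2 and 78 to 88 in the others.

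Across genes RNA changes ran against ATAC-seq changes and with promoter H3K27me3, with signs as the headers give them, though 43 genes with lower RNA also had lower ATAC-seq signal and 21 higher. A swap of the young and old columns in the ATAC-seq table alone is argued against by its positive correlation with H3K4me3 (rho 0.204). A reversed sign of the RNA comparison relative to the chromatin tables or a reversal of all chromatin tables, which would turn every chromatin direction given here, may account for the pattern, since RNA ran against ATAC-seq (rho −0.341) and with promoter H3K27me3 (rho 0.489, permutation p 1e-05, the smallest possible). H3K4me3 does not settle it, with a rho of −0.0185 and Pearson's r of −0.0954 (permutation p 0.0417, adjusted 0.0556) that reached −0.188 (adjusted p 0.00844) for RNA genes with adjusted p under 0.05, and neither does Pol2 (rho −0.0598). A difference of age in which RNA and accessibility part also stays open, untested.

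Nearly all called H3K4me3 and Pol2 peaks and most listed ATAC-seq peaks were lower in old cells. The deposited H3K27me3 values held no shift common to every assay on old chromatin, with a median change of 0.12. As their normalization is not given and may have recentred such a shift, this does not exclude it. A common scale shift of H3K4me3 and Pol2 stays open, because the bound set in advance on their correlation (rho 0.184) was wrong: a constant added to every change leaves it as it is. Lower signal over background in the old H3K4me3 libraries cannot be told apart from a real loss: fold and level had a rho of 0.0633 at promoters, between the bounds set for either answer, and −0.255 over all peaks. A loss with age stays open, untested, as no spike-in or value per sample was used here.

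The largest ATAC-seq changes lay close together. Of the 100 genes with the largest change relative to the median peak, 20% had another within 1 Mb, against a median of 10% and a 95th percentile of 17% in random sets (one-sided p 0.0165, 10000 draws). Segments of a mixed strain background that differ between the cohorts may give this, and the strain label, which reads 132-C67BL/6J, names no standard strain. Regulation of whole neighbourhoods cannot be told apart from it, since 100% of the 11 neighbouring pairs changed in the same direction where 85.3% would by chance (exact binomial p 0.174), as 92 of the 100 genes were higher. No genotype was analysed here, and an effect of age on such regions stays open.

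Of the 35 splits of the 8 ATAC-seq libraries into groups of 4, the real one alone (1 split) called 1143 peaks in edgeR with TMM. The highest other split called 0, with 621 peaks at an unadjusted p under 0.05 against 1353 in the real one. Without scaling the real split called 4069 and the highest other 2. Because the peaks were selected on the real grouping, these counts do not tell whether chance can be excluded.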

How the results depend on the processing

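The ATAC-seq fits without scaling and by column sums, the unscaled replicate block, the left-out libraries in the listed direction, the listed direction and ATAC-seq share at bivalent promoters, gene lists at promoters, and the matching of developmental promoters on level were chosen after seeing the data. Most alternatives kept direction and side of the threshold or a count within 1.5 times, while 34 counts moved further, 5 results fell below the threshold and 2 rose past it. No correlation or difference of medians between promoter classes reversed. The share of H3K4me3 promoter peaks called lower did reverse. It was 93.7% at bivalent and 94.4% at other promoters, and 93.7% and 89.4% matched on level. The balance of called peaks turned as well: ATAC-seq calls went from mostly higher with TMM to mostly lower without scaling. RNA turned from more higher to more lower genes at an absolute log2 fold change of at least 1, and H3K27me3 from slightly more higher to more lower peaks at an adjusted p under 0.01 and at a mean level of at least 50 (1497 lower, 1286 higher).

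With TMM, 55 ATAC-seq peaks were lower; this was 18 at an adjusted p under 0.01, 99 under 0.1, 34 with an absolute log2 fold change of at least 1, and 34 (without young replicate 3) to 60 with 1 library left out. Higher peaks (1088) kept within 1.5 times in DESeq2 (1082), voom (1089) and by column sums (1070). Without scaling there were 3643 lower and 426 higher peaks, and with 1 library left out 1409 to 3197 lower and 141 to 373 higher, the lowest without old replicate 3. The listed direction changed only without young replicate 4 (6730 lower, 1119 higher). Since peaks were selected on these libraries at an absolute log2 ratio of at least 0.50, this stability is no independent check.

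The replicate numbers do not pair the samples, since deviations of same-numbered libraries correlated at −0.0266, −0.109, 0.0354 and −0.186. With the replicate number as a block, 49 lower and 1055 higher peaks were called with TMM, and 755 and 91 without scaling; the cause was not tested. No paired analysis was possible for RNA and ChIP-seq because they hold no values per sample. For the same reason leaving out replicates, other normalizations, pseudocounts, voom, camera and fry were not run there, and their depth is unknown.

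By construction, other thresholds changed the deposited counts. At an adjusted p under 0.01 RNA had 32 lower and 81 higher genes, H3K27me3 931 lower and 661 higher peaks, H3K4me3 36 higher and Pol2 2192 lower. Under 0.1 RNA had 236 lower and 361 higher, H3K27me3 2916 higher and Pol2 6 higher. An absolute log2 fold change of at least 1 left 11 lower and 7 higher RNA genes and 810 lower H3K27me3 peaks. A mean level of at least 50 left 36 higher H3K4me3 peaks and 0 higher Pol2 peaks (DiffBind).

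Of the 2046 bivalent promoters, 1131 remained under an overlap of 50% and 860 in the stronger 50% of peaks, by construction. The ATAC-seq difference at bivalent promoters (−0.05) was −0.024 (permutation p 0.242) matched on level, and the Pol2 difference (0.85) was 0.50 (p 0.198). The share listed lower was 3.47 percentage points higher at bivalent promoters, and 2.82 with an overlap of 50% (Fisher's exact p 0.168), 4.13 in the stronger 50% (p 0.119) and 3.91 matched on level (p 0.0614). RNA and promoter ATAC-seq had a rho of −0.376 (permutation p 0.0504), −0.393 (p 0.0404) with the strongest promoter peak and −0.341 (p 3e-05) with any peak. The cause was not tested, except that fewer peaks enter the stricter overlaps. Developmental promoters led others in lower H3K27me3 calls by 49.6 percentage points, and by 37.3 matched on level.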

Other observations

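The RNA groups, the developmental promoters and both tests of gene length described here were chosen only after values were seen. Beyond the fixed lists, 6 groups of listed RNA genes were formed by what they encode. Each was compared by Fisher's exact test of direction with the other listed genes, leaving out the 43 ribosomal protein genes, all listed higher. Chaperones, which fold proteins, were listed higher in old cells for 14 of 15 genes, 10 of them called (adjusted p 0.00945), and the group holds members of the Hsp90, Hsp70 and chaperonin families. Translation factors were listed higher for 10 of 10, with 9 called (0.0126), and genes of the mitochondrial respiratory chain and mitochondrial ribosome for 14 of 15, with 10 called higher and 1 lower (0.00945). Genes of the major histocompatibility complex and its invariant chain gene Cd74 were listed lower for 5 of 5, with 2 called (Cd74, H2-M2, H2-Q5, H2-Eb1 and H2-Q4, adjusted p 0.0205). With the RNA sign reversed each of these directions would turn. Synaptic and axon guidance genes were split, 8 lower and 7 higher (0.435), and zinc finger genes had 5 lower and 14 higher (0.196).

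Within the developmental regulators, promoter H3K27me3 peaks were counted by family, with no test between the families. No family held a called increase. Called lower were 16 of 26 Fox peaks, 9 of 12 Nkx, 5 of 6 Lhx, 4 of 4 Zic, 3 of 4 Hox, 5 of 11 Tbx, 5 of 10 Sox, 4 of 13 Pax and 0 of 2 Cdx peaks. In ATAC-seq, 13 of the 14 listed promoter peaks of developmental regulators had lower counts in old cells, as had 94.3% of all listed promoter peaks. Foxa1 fell from 126 ± 27 to 51.8 ± 9.91 counts (SD, n = 4 each; edgeR FDR 0.0160 without scaling, 0.297 with TMM) and Sox21 from 2056 ± 91.2 to 1220.5 ± 138 (0.0041 and 0.917). Hoxa2 was the exception, with 179 ± 28.2 in young and 265 ± 64.9 in old libraries (SD, n = 4 each; edgeR FDR 0.0633 without scaling, 0.00314 with TMM).

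Ribosomal protein genes are short, and shorter genes may be higher in old cells whatever they encode. Outside that family 305 higher listed genes had a median length of 18197 bp and 211 lower ones 26192 bp (permutation p 0.00407). Of the 169 other listed genes no longer than the longest ribosomal gene, 65.1% were higher, against 43 of 43 (Fisher's exact p 1.72e-07). This does not settle whether length alone is the whole cause. The 169 genes were capped and not matched on length, and the ribosomal genes had a median of 3068 bp.

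A peak spanning the mitochondrial genome had an H3K27me3 level of 7.91 in young and 14.44 in old samples (log2, FDR 1.0) and a Pol2 level of 15.34 and 13.65 (FDR 0.728) in the authors' deposited table. Of the 60 H3K4me3 peaks called higher, 9 were on unplaced scaffolds and 3 on the Y chromosome. ATAC-seq counts summed over 6 peaks annotated to Erdr1 on the Y chromosome were 1808, 2002, 1438 and 1364 in young replicates 1 to 4 and 684, 646, 1350 and 1243 in old replicates 1 to 4. Over 7 peaks annotated to Rbmy or to the predicted genes Gm21708, Gm21704 and Gm21677 they were 6693, 6099, 6954 and 6468 in young replicates 1 to 4. In old replicates 1 to 4 they were 5556, 5747, 2718 and 3259. Of the other listed Y peaks, 3 of Rbm31y (log2 0.55, 0.61 and 1.20) and 1 of Gm16501 (0.78) had a higher mean in old libraries and 1 of Uty (−0.59) a lower one. At the Rbm31y peaks of 0.55 and 0.61 and at Gm16501, old replicate 3 (121, 111 and 155) lay within the range of the young libraries. The Y share of listed counts was 0.305% to 0.370% in young and 0.257% to 0.401% in old libraries.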
